A study of Drosophila melanogaster with 14 samples.

How the data were processed

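Tagged ribosomes with their RNA were purified (T-TRAP, named by the series) from wild-type Drosophila melanogaster photoreceptors at 7 pupal ages with 2 libraries each. Per the labels' protocols, 40 optic lobes with the retina attached and the central brain removed went into each replicate, the tag was driven by Chp-GAL4, and the RNA was amplified linearly (RiboAmp HS) before library construction. The labels do not state that replicates come from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Per the submitters' processing notes TopHat and the genome build BDGP5 were used, with no version or role. Counter, annotation, filters and use of the read strand are not stated.

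The authors deposited values in RPKM for 15682 genes in a single table with 14 columns. Each gene's values were checked to be whole multiples of 1 read per its length and library total, within 0.001 for 99.99% of the 13484 genes with any value, and the library totals recovered in this way equal the sum of recovered reads to at least 99.992%. RPKM is therefore scaled to reads assigned to genes, and no further scaling between libraries had been applied. Reads assigned to genes by library were 56741933 and 32555127 at 24 h, 9945709 and 16479278 at 35 h, and 16274364 and 17444811 at 40 h. They were 11949716 and 8871819 at 45 h, 14274021 and 12833941 at 53 h, 23390075 and 20652769 at 65 h, and 24805846 and 27404081 at 96 h. Gene lengths and names came from a BDGP6 annotation, to which 15002 identifiers were matched. The reads of 5650 genes were recovered with its length and those of 7833 with a length solved from the values.

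Genes with at least 1 RPKM in at least 2 libraries were tested (9228 genes), and 2198 genes were at 0 in every library. A linear model with 1 mean per age was fitted in limma 3.58.1 (R 4.3.3) to log2(RPKM + 1), with a variance trend, 7 residual and 5.36 prior degrees of freedom, and no block. Change over the 7 ages was tested with the moderated F test, and 8 contrasts with moderated t tests: 24 to 96 h, 35 to 53 h, and each pair of consecutive ages. Benjamini-Hochberg adjustment ran over all tested genes within a test, with a threshold of 0.05. Log2 changes on this scale understate changes of genes at low levels. With 1 kb of transcript and 1 read a gene stands between 0.0176 and 0.113 RPKM, and the 3-read levels given for genes at 0 cover counting error only.

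Gene lists (28 of pathways, other cell types and quality signs) were tested in each contrast with camera in limma at its preset correlation of 0.01, adjusted over lists, and also with an estimated correlation and with fry. Lists, tests, filters and contrasts were fixed before the data were examined, as was the rule for naming genes. That rule takes, per contrast, up to 6 largest rises and 6 largest falls among called genes with non-overlapping libraries, a mean of at least 10 RPKM and a gene symbol. It adds, per list with at least 2 called members, up to 3 called members and 1 that was not called, and 13 genes in every contrast, which are chp, ninaE, Rh3, Rh4, Rh5, Rh6, Hdc, brp, Syt1, elav, CadN, repo and ort. Some genes so named were left out for space, among them members of near-identical gene copies, whose reads cannot be assigned with certainty. Of 114 named genes found in the annotation, 6 have at least 15% of their exonic bases under exons of another gene (Hr46, Hsp67Ba, elav, ftz-f1, Traf4 and Obp44a).

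On simulated data with the spread of these libraries, 97 to 99 of 100 genes changed 4-fold and 48 to 62 of 100 changed 2-fold were recovered in each contrast, with 1 to 16 unchanged genes called. As many genes were raised as lowered, and all others kept the same mean over the ages. Calls that follow from a shift of all genes were therefore not simulated. Each gene also had the same spread at every age. In the real libraries the median replicate difference (log2, over the square root of 2) was 0.29 at 45 h and 0.106 to 0.149 at the other ages. The simulated counts therefore do not describe the contrasts with 45 h. By contrast the 2-fold recoveries were 51 (24 to 96 h), 51 (35 to 53 h), 62 (24 to 35 h), 60 (35 to 40 h), 50 (40 to 45 h), 55 (45 to 53 h), 58 (53 to 65 h) and 48 (65 to 96 h). A simulated changed list was called in each contrast and 0 of 27 random lists were. Genes were simulated as independent of each other, so this cannot show how often camera calls lists of correlated genes. The alternatives tried were quantile normalization, no filter, a filter at 10 RPKM, no variance trend, weights for libraries, pseudocounts of 0.1 and 5, the replicate number as a block, each library left out in turn, and only the 4 libraries of a contrast. After the data had been seen, median-ratio scaling, limma-voom on the recovered reads, fits without both 40 h or both 45 h libraries, and fits with only the libraries of 40 h and later or only those of 24 and 35 h were added. Counts of a list after median-ratio scaling are given where scaling turned the majority or put calls in a direction that had 0. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.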

Results

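RNA bound to tagged ribosomes was measured in photoreceptors (R cells) of the fruit fly Drosophila melanogaster at 7 ages of pupal life between 24 and 96 h after puparium formation (APF). The tag was driven by Chp-GAL4, a driver of photoreceptors, and each of the 14 libraries (2 per age) came from 40 optic lobes with their retinas. Levels are in RPKM (reads scaled to gene length and library size), and 1 read on a gene of 1 kb stood between 0.0176 RPKM in the deepest library and 0.113 RPKM in the shallowest. They are given as the mean ± SD of the 2 libraries of an age, and changes are log2 changes ± SE from limma (n = 2 libraries per age). The question put by the series is how the transcriptome of these neurons changes while their circuits assemble.

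The 2 libraries of an age had a correlation of log2 levels across genes between 0.969 at 45 h and 0.994 at 40 h, genes not being independent replicates. All 14 libraries were closest to the other library of their own age. No pair agreed within sampling noise, with chi-square values per degree of freedom from 26.9 to 142. At 45 h replicate 1 held 19.3% ribosomal protein reads and replicate 2 10.8%, the widest gap within an age.

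Of 9228 genes tested, 8888 (96.3%) changed over the 7 ages (limma moderated F test, Benjamini-Hochberg adjusted p under 0.05, with 8895 at an unadjusted p under 0.05). The highest and lowest mean levels differed by at least 2 on the log2 scale for 5321 of these. In RPKM as deposited 2663 genes had their highest level at 24 h, 1432 at 35 h and 1285 at 96 h, and 4048 genes had their lowest level at 96 h. After median-ratio scaling these counts were 1676, 1062 and 2566, and 2010 lowest at 96 h. The most abundant transcript was RpL10Ab, a protein of the large ribosomal subunit, at 24 h (11586 ± 1455 RPKM). RpL23 led at 35 h, and RpL41 in both libraries of 40 h and replicate 1 of 45 h. At 53 and 65 h the lead passed to CG34138, an uncharacterised gene, with 17011 and 17195 RPKM at 53 h and 70525 and 72464 RPKM at 65 h. At 96 h the lead was held by ninaE (56557 ± 7942 RPKM), the gene of the Rh1 opsin of the outer photoreceptors. Apart from ninaE, these most abundant genes were chosen after their values were seen.

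**Figure D1:**
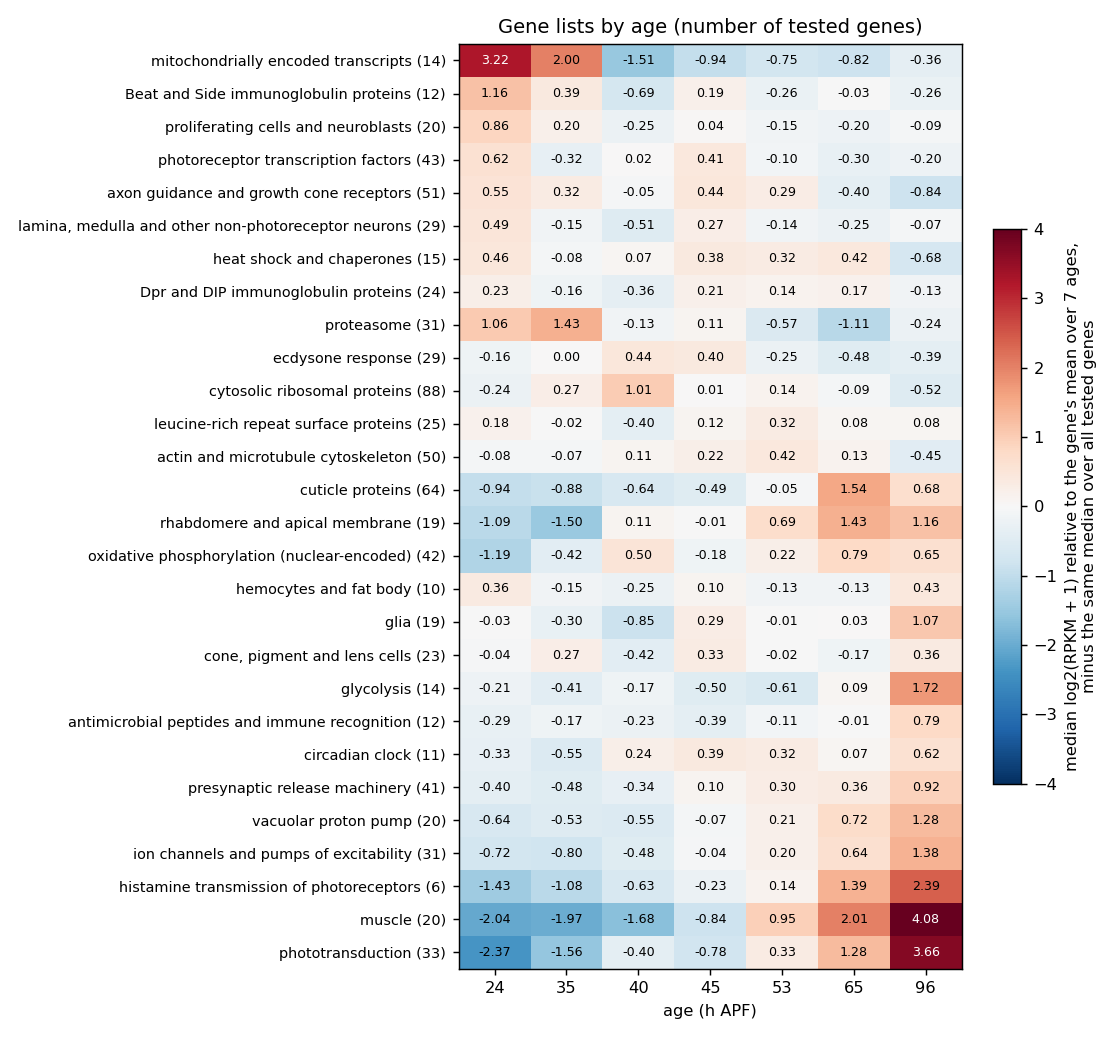
Median log2(RPKM + 1) of each gene list (vertical axis, number of tested genes in brackets) at each age (horizontal axis, h APF), relative to each gene's own mean over the 7 ages and to all tested genes (colour and printed value). Phototransduction goes from -2.37 at 24 h to 3.66 at 96 h and muscle from -2.04 to 4.08, while mitochondrially encoded transcripts drop from 2 at 35 h to -1.51 at 40 h.

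Between 24 and 96 h genes of light detection were among those with the largest rises. Levels of ninaE went from 0.432 ± 0.0961 to 56557 ± 7942 RPKM, a log2 change of 15.26 ± 0.24 (adjusted p = 1.86e-13). Arr2, the main arrestin that shuts off rhodopsin, rose by 13.50 ± 0.19 to 17965 ± 1092 RPKM. The main light-activated channel gene, trp, reached 2231 ± 138 RPKM from a single read over both 24 h libraries. The opsins of the inner photoreceptors rose as well. The R7 opsin Rh4 rose by 11.49 ± 0.24 and the R8 opsins Rh5 and Rh6 by 9.34 ± 0.20 and 8.17 ± 0.21. The R7 opsin Rh3 went from 0 reads to 3766 ± 24.4 RPKM, at least 157000-fold above the level that 3 reads over both 24 h libraries would give. Of 33 tested phototransduction genes, 28 rose, 2 fell and 3 did not pass the test (28 and 2 adjusted over the list alone). Their median change lay 6.03 above that of all genes (camera adjusted p = 1.34e-19, adjusted p = 0.0299 with an estimated correlation).

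The membrane protein prominin, encoded by prom, rose by 7.73 ± 0.18 and eys, which opens the space between rhabdomeres, by 7.25 ± 0.31, to 221 ± 10.6 RPKM. ninaC, a myosin of the rhabdomere, rose by 6.92 ± 0.21 and chp, the photoreceptor surface protein chaoptin, by 3.20 ± 0.21 from an already high 603 ± 58.3 RPKM. In the list of the rhabdomere and apical membrane (19 genes) 11 rose, 6 fell and 2 did not pass the test (11 and 6 adjusted over the list alone), with camera adjusted p = 0.000352, adjusted p = 0.279 with an estimated correlation. Hdc, the histidine decarboxylase that makes the photoreceptor transmitter, rose by 6.92 ± 0.27. In the list of histamine transmission 5 of 6 genes rose, 0 fell and 1 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.000113, adjusted p = 0.0299 with an estimated correlation).

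The vesicle proteins synaptogyrin, n-syb and cpx rose by 5.13 ± 0.17, 4.37 ± 0.19 and 3.85 ± 0.26, and Syt1, the calcium sensor of release, by 2.26 ± 0.21. In contrast brp, a scaffold of the active zone, fell by 0.88 ± 0.23, a direction that turned under median-ratio scaling (0.17). Of 41 presynaptic genes, 18 rose, 11 fell and 12 did not pass the test (18 and 11 adjusted over the list alone), with camera adjusted p = 0.000341, adjusted p = 0.533 with an estimated correlation. The potassium channel genes eag and slo rose by 5.15 ± 0.24 and 4.16 ± 0.28. Of 31 genes of ion channels and pumps 24 rose, 4 fell and 3 did not pass the test (24 and 4 adjusted over the list alone, camera adjusted p = 1.52e-08, adjusted p = 0.185 with an estimated correlation). CoIV and CoVb, nuclear genes of oxidative phosphorylation, rose by 2.73 ± 0.19 and 2.81 ± 0.23. Of 42 tested members of their list 28 rose, 4 fell and 10 did not pass the test (28 and 4 adjusted over the list alone, camera adjusted p = 1.82e-08, adjusted p = 0.177 with an estimated correlation). Their median, relative to all genes, was -1.19 at 24 h, -0.42 at 35 h, 0.5 at 40 h and 0.65 at 96 h, with little net rise after 40 h.

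Over the same interval the Wnt5 receptor gene drl fell by 7.26 ± 0.17 from 702 ± 106 to 3.56 ± 0.457 RPKM, and the adhesion gene Fas3 and the receptor gene otk had changes of -6.07 ± 0.22 and -5.24 ± 0.21. In the axon guidance list (51 genes) 4 rose, 40 fell and 7 did not pass the test (4 and 41 adjusted over the list alone), with camera adjusted p = 0.00172, adjusted p = 0.639 with an estimated correlation. Among Beat and Side proteins, adhesion molecules of the immunoglobulin family, 0 of 12 genes rose, 11 fell and 1 did not pass (0 and 11 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.465 with an estimated correlation). Relative to all genes, the Beat and Side median was 1.16 at 24 h, 0.39 at 35 h, -0.69 at 40 h and -0.26 at 96 h. There was thus no net fall after 40 h. The homeodomain gene ro, active in the differentiating eye, changed by -5.97 ± 0.23. Of 43 genes listed as photoreceptor transcription factors 2 rose, 32 fell and 9 did not pass the test (2 and 32 adjusted over the list alone, camera adjusted p = 0.0133, adjusted p = 0.533 with an estimated correlation). That list also holds elav, a pan-neuronal gene of an RNA-binding protein, so it is not made up of photoreceptor transcription factors alone. Rpn11, a proteasome subunit that removes ubiquitin, fell by 4.22 ± 0.24. In its list 0 of 31 genes rose, 31 fell and 0 did not pass (0 and 31 adjusted over the list alone, 1 and 23 after median-ratio scaling, camera adjusted p = 2.52e-05, adjusted p = 0.168 with an estimated correlation), with a median -1.48 relative to all genes. By age the list median, relative to all genes, was 1.43 at 35 h, -0.13 at 40 h, -1.11 at 65 h and -0.24 at 96 h. From 40 to 96 h there was thus little net fall, and from 35 to 40 h the share of mitochondrial reads changed as well. The small heat shock genes Hsp27 and Hsp23 fell by 10.24 ± 0.54 and 8.47 ± 0.57. In the chaperone list 1 of 15 genes rose, 9 fell and 5 did not pass (1 and 9 adjusted over the list alone, camera adjusted p = 0.076, adjusted p = 0.533 with an estimated correlation). Among ribosomal proteins 2 of 88 genes rose, 68 fell and 18 did not pass (2 and 68 adjusted over the list alone, camera adjusted p = 0.0351, adjusted p = 0.783 with an estimated correlation), with a median of -1.31 (-0.39 relative to all genes), a direction that flipped under median-ratio scaling to 23 higher and 11 lower with a median of 0.16.

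Markers of cells other than photoreceptors did not move as one. Muscle genes rose, with Mlc2, a myosin light chain, at 8.57 ± 0.28 and 729.8 ± 98.5 RPKM at 96 h. Of 20 tested members 19 rose, 1 fell and 0 did not pass the test (19 and 1 adjusted over the list alone, camera adjusted p = 1.34e-13, adjusted p = 0.0299 with an estimated correlation). In the list of glia 6 rose, 8 fell and 5 did not pass the test (6 and 8 adjusted over the list alone, 11 and 6 after median-ratio scaling), where the glutamine synthetase gene Gs2 rose by 4.18 ± 0.23 and wrapper changed by -3.72 ± 0.22 (camera adjusted p = 0.35, adjusted p = 0.752 with an estimated correlation). The largest change of the glial list was that of Obp44a, at -4.64 ± 0.28, from 7462 ± 180 to 298.7 ± 7.56 RPKM. The median of the glial list was 0.01 (0.94 relative to all genes, 1.42 after scaling) and its mean -0.35. Of 20 genes of proliferating cells, 0 rose, 19 fell and 1 did not pass the test (0 and 19 adjusted over the list alone, 1 and 17 after median-ratio scaling), among them the mitotic phosphatase gene stg at -5.58 ± 0.24 (camera adjusted p = 0.00333, adjusted p = 0.168 with an estimated correlation). The median of that list, relative to all genes, was 0.86 at 24 h, 0.2 at 35 h, -0.25 at 40 h and -0.09 at 96 h, with no net fall after 40 h. The lens genes Cpr72Ec and retinin rose by 7.80 ± 0.33 and 7.77 ± 0.21. Of 23 genes of cone, pigment and lens cells 10 rose, 12 fell and 1 did not pass the test (10 and 12 adjusted over the list alone, 12 and 9 after median-ratio scaling, camera adjusted p = 0.24, adjusted p = 0.394 with an estimated correlation). Their median was -0.63 (0.30 relative to all genes) and their mean 0.35. In the cuticle list, which its name pattern also fills with some accessory gland proteins, 37 of 64 genes rose, 9 fell and 18 did not pass (37 and 8 adjusted over the list alone, camera adjusted p = 4.09e-11, adjusted p = 0.0299 with an estimated correlation). Of 14 mitochondrially encoded transcripts 0 rose, 13 fell and 1 did not pass the test (0 and 13 adjusted over the list alone), with mt:CoI at -8.47 ± 0.33 (camera adjusted p = 0.00333, adjusted p = 0.465 with an estimated correlation).

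In all, 7361 genes were called between 24 and 96 h, 2002 higher and 5359 lower, and the median of all genes shifted by -0.92. With median-ratio scaling between libraries the split was 3725 higher and 3125 lower, and 352 genes were called in the opposite direction. The 24 and 35 h libraries differed from all later ones in mitochondrial reads, and among the later libraries alone the change from 40 to 96 h called 2185 genes higher and 4599 lower (3572 and 2952 after scaling).

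**Figure D2:**
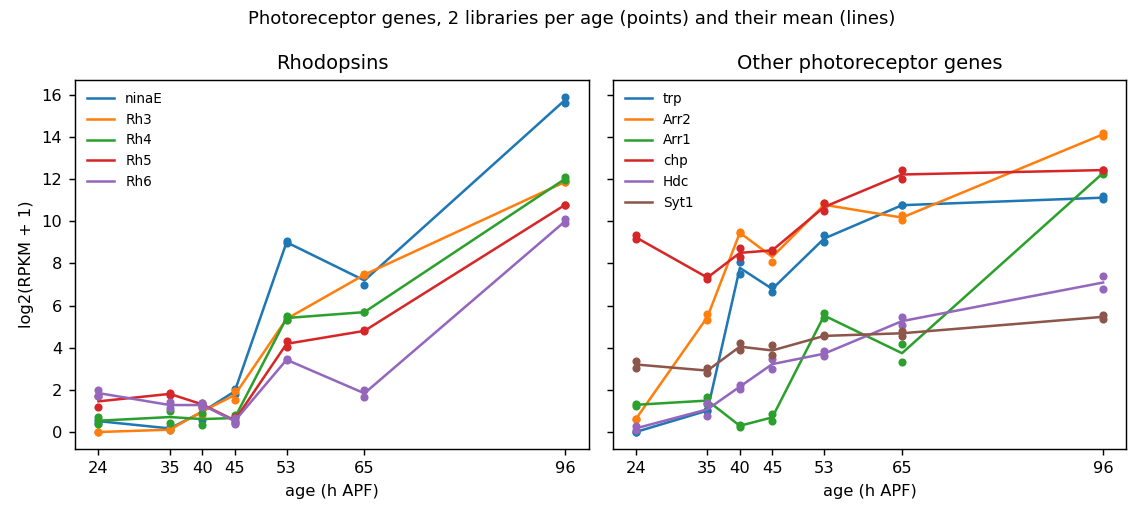
Levels as log2(RPKM + 1) (vertical axis) against age in h APF (horizontal axis) for opsin genes (left) and other photoreceptor genes (right), with points for each of 2 libraries per age and lines through their mean. ninaE rises from 2.82 ± 0.504 RPKM at 45 h to 513 ± 25.4 RPKM at 53 h, dips at 65 h and ends at 56557 ± 7942 RPKM at 96 h.

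In the most densely sampled stretch, 35 to 53 h, the tetraspanin gene Tsp47F went from a single read to 3293 ± 154 RPKM, and the cuticle gene Cpr66Cb from 0 reads to 728 ± 192 RPKM, at least 6420-fold above the 3-read level of the 35 h libraries. The lens crystallin gene Cry (a different gene from the clock gene cry) reached 520.4 ± 8.06 RPKM. ninaE rose by 8.84 ± 0.24 to 513 ± 25.4 RPKM, trp by 8.17 ± 0.20 to 584 ± 90 RPKM and chp by 3.35 ± 0.21 (adjusted p = 7.85e-08). Cht5, a chitinase, fell by 7.81 ± 0.28, and ImpE2 and ImpL1, genes induced by the moulting hormone ecdysone, by 6.76 ± 0.28 and 5.54 ± 0.57.

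Of 33 phototransduction genes 25 rose, 1 fell and 7 did not pass the test (25 and 1 adjusted over the list alone), with a median 1.80 above that of all genes (camera adjusted p = 2.05e-11, adjusted p = 0.0757 with an estimated correlation). In the rhabdomere list 13 rose, 2 fell and 4 did not pass the test (13 and 2 adjusted over the list alone, camera adjusted p = 2.04e-06, adjusted p = 0.232 with an estimated correlation). Relative to all genes, the rhabdomere median was -1.5 at 35 h, 0.11 at 40 h and 0.69 at 53 h. That of phototransduction was -1.56, -0.4 and 0.33 at these ages. Most of both rises thus lay between 35 and 40 h, where the share of mitochondrial reads changed as well. The rhabdomere genes eys and Amph, encoding amphiphysin, rose by 5.76 ± 0.31 and 3.76 ± 0.30. Hdc rose by 2.64 ± 0.27. For histamine transmission 5 of 6 genes rose, 0 fell and 1 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.00604, adjusted p = 0.0912 with an estimated correlation). Of 41 presynaptic genes 21 rose, 5 fell and 15 did not pass the test (21 and 6 adjusted over the list alone, camera adjusted p = 0.000254, adjusted p = 0.701 with an estimated correlation). The active-zone gene Rbp rose by 3.82 ± 0.30 to 20.5 ± 2.34 RPKM and brp by 0.85 ± 0.23. Among channels and pumps 18 rose, 5 fell and 8 did not pass the test (18 and 6 adjusted over the list alone, camera adjusted p = 0.000254, adjusted p = 0.478 with an estimated correlation). The calcium-activated potassium channel gene slo rose by 4.09 ± 0.28.

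The proteasome subunit gene Rpn12 fell by 3.79 ± 0.20. In its list 0 of 31 genes rose, 30 fell and 1 did not pass (0 and 30 adjusted over the list alone, camera adjusted p = 2.05e-11, adjusted p = 0.0757 with an estimated correlation), with a median -1.99 relative to all genes. By age the list median, relative to all genes, was 1.43 at 35 h, -0.13 at 40 h and -0.57 at 53 h, so most of this fall lay between 35 and 40 h. Among cuticle proteins 29 of 64 genes rose, 5 fell and 30 did not pass (29 and 5 adjusted over the list alone, camera adjusted p = 6.67e-08, adjusted p = 0.0757 with an estimated correlation). Of the muscle list 17 of 20 genes rose, 1 fell and 2 did not pass (17 and 1 adjusted over the list alone, camera adjusted p = 2.23e-09, adjusted p = 0.0757 with an estimated correlation). Among mitochondrially encoded transcripts 0 of 14 genes rose, 12 fell and 2 did not pass (0 and 12 adjusted over the list alone, camera adjusted p = 5.91e-06, adjusted p = 0.37 with an estimated correlation). Of 29 ecdysone response genes 7 rose, 11 fell and 11 did not pass the test (7 and 11 adjusted over the list alone, camera adjusted p = 0.714, adjusted p = 0.926 with an estimated correlation). Surface proteins of the Dpr and DIP families, partners in synaptic matching, went both ways: dpr9 rose by 2.80 ± 0.23, dpr12 fell by 1.77 ± 0.23. In the list 6 of 24 genes rose, 5 fell and 13 did not pass (6 and 5 adjusted over the list alone, camera adjusted p = 0.578, adjusted p = 0.935 with an estimated correlation). Leucine-rich repeat surface proteins also split, since 6 of 25 genes rose, 7 fell and 12 did not pass (6 and 7 adjusted over the list alone, 11 and 6 after median-ratio scaling, camera adjusted p = 0.24, adjusted p = 0.922 with an estimated correlation).

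The interval called 5356 genes, 1954 higher and 3402 lower, with a median shift of -0.23, and median-ratio scaling gave 2579 higher and 2569 lower. Within the libraries of 40 h and later, the change from 40 to 53 h called 2189 higher and 2364 lower (2372 and 2242 after scaling).

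**Figure D3:**
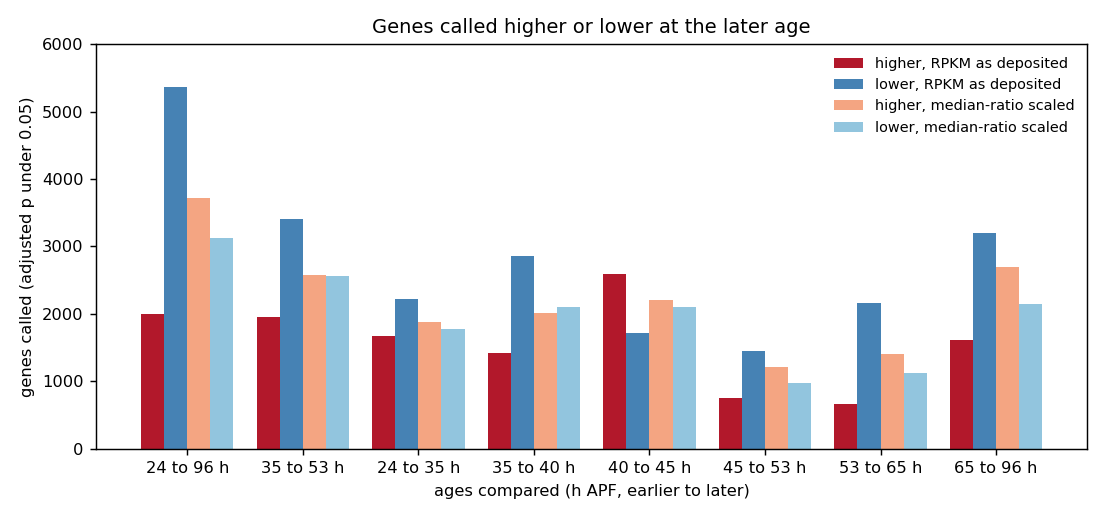
Number of genes called (vertical axis, adjusted p under 0.05) as higher or lower at the later of the ages compared (horizontal axis, h APF), with dark bars for RPKM as deposited and light bars after median-ratio scaling. From 24 to 96 h the split is 2002 higher and 5359 lower as deposited, and 3725 higher and 3125 lower after scaling.

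From 24 to 35 h E(spl)m8-HLH and E(spl)mgamma-HLH, repressors switched on by Notch, fell by 3.74 ± 0.19 and 3.80 ± 0.22, and Traf4 by 3.28 ± 0.20. The nuclear receptor genes Hr46 and Hr4 rose by 4.35 ± 0.31 and 4.18 ± 0.24, to 20.5 ± 0.507 and 35.1 ± 2.08 RPKM, and ImpL1 by 6.19 ± 0.57 (adjusted p = 6.08e-06). The value of Hr46 is uncertain, since 82.7% of its exonic bases lie under exons of other genes on its strand. In the ecdysone list 6 rose, 7 fell and 16 did not pass the test (7 and 8 adjusted over the list alone, 8 and 6 after median-ratio scaling, camera adjusted p = 0.563, adjusted p = 0.906 with an estimated correlation), with a median of -0.02 and a mean of 0.40. CadN, the N-cadherin that photoreceptor axons need to find their targets, rose by 2.95 ± 0.29 from 1.96 ± 0.45 to 21.8 ± 1.82 RPKM, and the guidance genes tutl and Sema-1a rose by 3.70 ± 0.27 and 2.37 ± 0.30.

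More guidance genes went down than up. Of 51 tested members 8 rose, 22 fell and 21 did not pass the test (10 and 25 adjusted over the list alone, camera adjusted p = 0.171, adjusted p = 0.906 with an estimated correlation). Among Beat and Side proteins 1 of 12 genes rose, 8 fell and 3 did not pass (1 and 8 adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.906 with an estimated correlation). The riser was side (1.78 ± 0.20), whose protein binds Beat proteins. For photoreceptor transcription factors 1 of 43 genes rose, 23 fell and 19 did not pass (1 and 23 adjusted over the list alone, camera adjusted p = 0.00029, adjusted p = 0.906 with an estimated correlation). Among them nerfin-1, a zinc-finger gene of young neurons, fell by 2.31 ± 0.15. chp itself changed by -1.91 ± 0.21, and elav, the pan-neuronal RNA-binding protein gene, by -1.16 ± 0.25. Arr2 rose by 4.83 ± 0.19. In the phototransduction list 11 of 33 genes rose, 5 fell and 17 did not pass (12 and 5 adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.906 with an estimated correlation). For nuclear-encoded oxidative phosphorylation 20 of 42 genes rose, 0 fell and 22 did not pass (21 and 0 adjusted over the list alone, camera adjusted p = 2.98e-05, adjusted p = 0.906 with an estimated correlation).

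In the glial list 0 of 19 genes rose, 10 fell and 9 did not pass (0 and 10 adjusted over the list alone, 1 and 7 after median-ratio scaling, camera adjusted p = 0.0218, adjusted p = 0.906 with an estimated correlation). Among markers of lamina, medulla and other neurons 2 of 29 genes rose, 16 fell and 11 did not pass (2 and 16 adjusted over the list alone, camera adjusted p = 0.00153, adjusted p = 0.906 with an estimated correlation). VAChT, the vesicular transporter of acetylcholine, a transmitter that photoreceptors do not use as their main one, changed by -2.51 ± 0.20. Among proliferation genes 2 of 20 genes rose, 10 fell and 8 did not pass (2 and 10 adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.906 with an estimated correlation). In all 3899 genes were called, 1674 higher and 2225 lower, and median-ratio scaling gave 1876 higher and 1779 lower.

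Between 35 and 40 h levels of trp went from 1.02 ± 0.0611 to 225 ± 62 RPKM (6.78 ± 0.20, adjusted p = 2.96e-10), Arr2 rose by 4.00 ± 0.19, and inaD, the scaffold of the phototransduction complex, by 2.78 ± 0.21. Osi7 and Osi1, of the insect-specific Osiris family of membrane proteins, rose by 5.96 ± 0.62 and 5.82 ± 0.64. The ecdysone-induced nuclear receptor gene Eip75B rose by 2.25 ± 0.28, to 146 ± 30.4 RPKM. Of 33 phototransduction genes 16 rose, 1 fell and 16 did not pass the test (16 and 1 adjusted over the list alone, camera adjusted p = 6.69e-07, adjusted p = 0.333 with an estimated correlation). Of 19 rhabdomere genes 13 rose, 1 fell and 5 did not pass the test (13 and 1 adjusted over the list alone, camera adjusted p = 2.38e-06, adjusted p = 0.333 with an estimated correlation).

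The proteasome subunit genes Pros35 and Prosbeta1 fell by 2.69 ± 0.21 and 2.57 ± 0.23. In their list 0 of 31 genes rose, 30 fell and 1 did not pass (0 and 31 adjusted over the list alone, camera adjusted p = 5.63e-13, adjusted p = 0.154 with an estimated correlation). For nuclear-encoded oxidative phosphorylation 23 of 42 genes rose, 1 fell and 18 did not pass (23 and 1 adjusted over the list alone, camera adjusted p = 4.17e-08, adjusted p = 0.333 with an estimated correlation). Among ribosomal proteins 30 of 88 genes rose, 6 fell and 52 did not pass (29 and 5 adjusted over the list alone, camera adjusted p = 1.72e-06, adjusted p = 0.825 with an estimated correlation). The mitochondrial transcripts mt:lrRNA and mt:CoI fell by 9.73 ± 0.49 and 7.98 ± 0.33. In their list 0 of 14 genes rose, 12 fell and 2 did not pass (0 and 12 adjusted over the list alone, camera adjusted p = 1.15e-08, adjusted p = 0.333 with an estimated correlation). The mitochondrial share of reads was 0.524 to 0.862% in the 4 libraries of 24 and 35 h and at most 0.008% in the 10 later ones, and the ribosomal RNA share at least 0.281% against at most 0.001%. The ribosomal RNA share includes mt:lrRNA (3372 ± 283 RPKM at 35 h), which also counts in the mitochondrial share. The 2 shares are therefore not separate signs, and they do not show a loss of cytosolic ribosomal RNA. The age step and this step in library make-up cannot be separated for any change between 35 and 40 h.

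In the same step Obp44a, an odorant-binding protein gene of the glial list, fell by 3.40 ± 0.28 from 2862 ± 1053 to 273 ± 109 RPKM and repo, the glial transcription factor gene, by 1.06 ± 0.21. In that list 0 of 19 genes rose, 13 fell and 6 did not pass (0 and 13 adjusted over the list alone, camera adjusted p = 0.00161, adjusted p = 0.333 with an estimated correlation). Among markers of lamina, medulla and other neurons 2 of 29 genes rose, 15 fell and 12 did not pass (2 and 15 adjusted over the list alone, camera adjusted p = 0.0456, adjusted p = 0.639 with an estimated correlation). Among proliferation genes 1 of 20 genes rose, 12 fell and 7 did not pass (1 and 12 adjusted over the list alone, camera adjusted p = 0.0456, adjusted p = 0.333 with an estimated correlation). The Beat gene beat-Vb fell by 2.56 ± 0.21. In its family 0 of 12 genes rose, 12 fell and 0 did not pass (0 and 12 adjusted over the list alone, camera adjusted p = 0.000437, adjusted p = 0.333 with an estimated correlation). For hemocytes and fat body 0 of 10 genes rose, 3 fell and 7 did not pass (0 and 3 adjusted over the list alone, camera adjusted p = 0.558, adjusted p = 0.85 with an estimated correlation). In all 4270 genes were called, 1418 higher and 2852 lower, with a median shift of -0.20, and median-ratio scaling gave 2016 higher and 2100 lower.

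**Figure D4:**
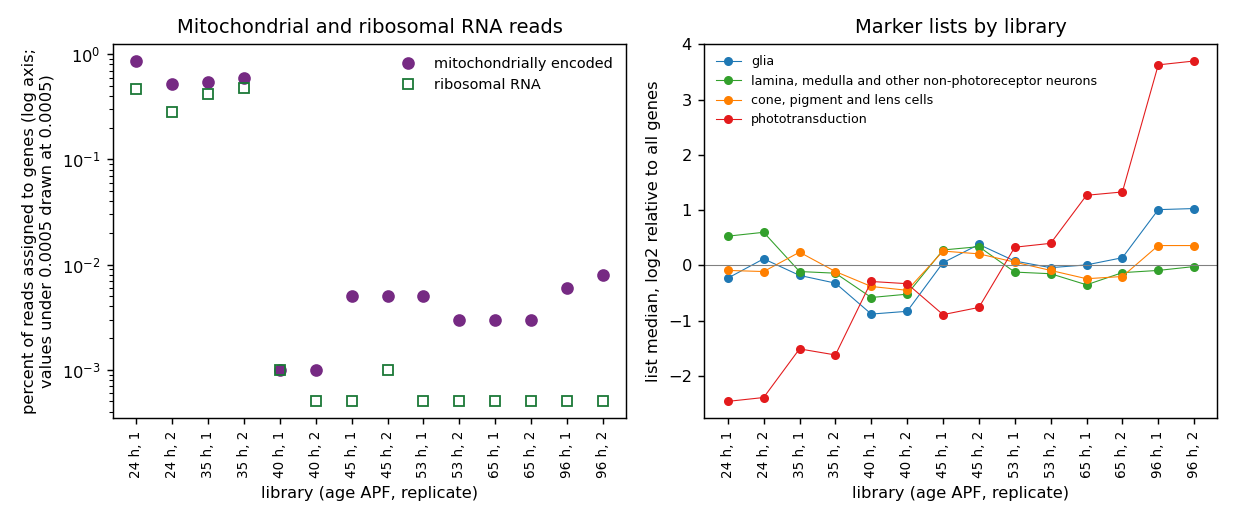
Left, percent of reads from mitochondrially encoded transcripts and ribosomal RNA in each library (logarithmic vertical axis), at least 0.524% and 0.281% at 24 and 35 h and at most 0.008% and 0.001% later. Reads of the mitochondrial mt:lrRNA count in both shares. Right, median of marker lists in each library as log2 relative to all genes, with glia at their lowest, -0.88 and -0.83, in the 40 h libraries.

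From 40 to 45 h Obp44a rose by 2.24 ± 0.28 to 1245 ± 199.9 RPKM, Gs2 by 3.28 ± 0.23 and moody, a receptor of the glial blood-brain barrier, by 3.43 ± 0.30 (adjusted p = 4.59e-06). The gene ort, a histamine receptor of the neurons that photoreceptors contact, rose by 1.70 ± 0.25 from 0.346 ± 0.153 RPKM, with no called fall before. Of 19 glial genes 16 rose, 0 fell and 3 did not pass the test (16 and 0 adjusted over the list alone, camera adjusted p = 5.92e-05, adjusted p = 0.614 with an estimated correlation). Among markers of lamina, medulla and other neurons 23 of 29 genes rose, 0 fell and 6 did not pass (25 and 0 adjusted over the list alone, 23 and 1 after median-ratio scaling, camera adjusted p = 1.71e-05, adjusted p = 0.614 with an estimated correlation). Among Beat and Side proteins 12 of 12 genes rose, 0 fell and 0 did not pass (12 and 0 adjusted over the list alone, camera adjusted p = 0.000881, adjusted p = 0.68 with an estimated correlation). Among Dpr and DIP proteins 13 of 24 genes rose, 2 fell and 9 did not pass (14 and 2 adjusted over the list alone, camera adjusted p = 0.0195, adjusted p = 0.68 with an estimated correlation). For axon guidance 21 of 51 genes rose, 3 fell and 27 did not pass (23 and 3 adjusted over the list alone, camera adjusted p = 0.045, adjusted p = 0.772 with an estimated correlation). Relative to all genes, the axon guidance median was -0.05 and -0.07 in the 40 h libraries and 0.22 and 0.7 in those of 45 h. That of Dpr and DIP proteins was -0.4 in both 40 h libraries and 0 and 0.42 in those of 45 h.

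The lens genes Cry and Cpr66D rose by 5.23 ± 0.27 and 3.85 ± 0.36, and the chitin-binding protein genes verm and Gasp by 4.80 ± 0.35 and 4.72 ± 0.24. The ribosomal protein gene RpL7A fell by 3.34 ± 0.22, from 6112 ± 606 to 617 ± 188 RPKM. In its list 1 of 88 genes rose, 49 fell and 38 did not pass (1 and 50 adjusted over the list alone, camera adjusted p = 1.42e-10, adjusted p = 0.68 with an estimated correlation), the share of such reads differing between the 45 h libraries. For nuclear-encoded oxidative phosphorylation 2 of 42 genes rose, 22 fell and 18 did not pass (2 and 22 adjusted over the list alone, camera adjusted p = 9.23e-05, adjusted p = 0.68 with an estimated correlation). The median of that list, relative to all genes, was 0.44 and 0.53 in the 40 h libraries and 0.14 and -0.54 in those of 45 h. The tyrosine kinase gene Abl, which acts in axon guidance, fell by 3.17 ± 0.20. Synapsin (Syn) rose by 1.98 ± 0.27. In the presynaptic list 20 of 41 genes rose, 3 fell and 18 did not pass (20 and 3 adjusted over the list alone, camera adjusted p = 0.0377, adjusted p = 0.757 with an estimated correlation). Its median, relative to all genes, was -0.27 and -0.46 in the 40 h libraries and -0.16 and 0.36 in replicates 1 and 2 of 45 h. The rise thus rested mostly on replicate 2 of 45 h. Of the muscle list 12 of 20 genes rose, 1 fell and 7 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.68 with an estimated correlation). The phototransduction median, relative to all genes, went from -0.4 at 40 h to -0.78 at 45 h, the only consecutive step in which it dropped. The comparison called 4310 genes, 2590 higher and 1720 lower, the median shift was 0.13, median-ratio scaling gave 2202 higher and 2099 lower, and quantile normalization 2026 higher and 2122 lower. Fitted on the 4 libraries of these ages alone, 1726 genes were called.

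Between 45 and 53 h ninaE rose by 7.08 ± 0.24 (adjusted p = 1.99e-09), Arr1, the other visual arrestin, by 4.83 ± 0.26 to 45.3 ± 5.86 RPKM, and the opsin genes Rh3, Rh4, Rh5 and Rh6 by 3.62 ± 0.19, 4.75 ± 0.24, 3.63 ± 0.20 and 2.91 ± 0.21. The cuticle gene Cpr62Bc went from 0.656 ± 0.197 to 1491 ± 171 RPKM, and Cpr76Bd from 0 reads to 43 ± 2.27 RPKM, at least 1350-fold above the 3-read level of the 45 h libraries. Osi6 and Osi7 fell by 7.38 ± 0.91 and 6.91 ± 0.62, from 976 ± 323 to 8.13 ± 6.42 RPKM for Osi7.

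Of 33 phototransduction genes 21 rose, 1 fell and 11 did not pass the test (21 and 1 adjusted over the list alone, camera adjusted p = 1.37e-14, adjusted p = 0.0586 with an estimated correlation). The early eye genes eya and ro fell by 1.91 ± 0.29 and 1.69 ± 0.23. Among photoreceptor transcription factors 0 of 43 genes rose, 18 fell and 25 did not pass (0 and 20 adjusted over the list alone, camera adjusted p = 0.00103, adjusted p = 0.448 with an estimated correlation). ImpL1 fell by 5.16 ± 0.57. In the ecdysone list 2 of 29 genes rose, 14 fell and 13 did not pass (3 and 15 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.31 with an estimated correlation). Among cuticle proteins 27 of 64 genes rose, 5 fell and 32 did not pass (27 and 7 adjusted over the list alone, camera adjusted p = 3.53e-11, adjusted p = 0.0586 with an estimated correlation). Of the muscle list 14 of 20 genes rose, 1 fell and 5 did not pass (15 and 1 adjusted over the list alone, camera adjusted p = 2.11e-10, adjusted p = 0.0609 with an estimated correlation). In the proteasome 0 of 31 genes rose, 20 fell and 11 did not pass (0 and 23 adjusted over the list alone, camera adjusted p = 6.6e-07, adjusted p = 0.198 with an estimated correlation). The histamine receptor gene ort fell by 1.62 ± 0.25 while repo had -0.47 ± 0.21 (adjusted p = 0.127). In the glial list 0 of 19 genes rose, 6 fell and 13 did not pass (1 and 6 adjusted over the list alone, 1 and 5 after median-ratio scaling, camera adjusted p = 0.306, adjusted p = 0.751 with an estimated correlation). Among markers of lamina, medulla and other neurons 1 of 29 genes rose, 13 fell and 15 did not pass (1 and 15 adjusted over the list alone, camera adjusted p = 0.00214, adjusted p = 0.38 with an estimated correlation). In all 2200 genes were called, 746 higher and 1454 lower, with a median shift of -0.13, and median-ratio scaling gave 1207 higher and 972 lower. This count depended on the fit: 206 genes were called with the 4 libraries alone (eya, ro and ort not among them), 844 with weights for libraries and 1321 without replicate 1 of 53 h.

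**Figure D5:**
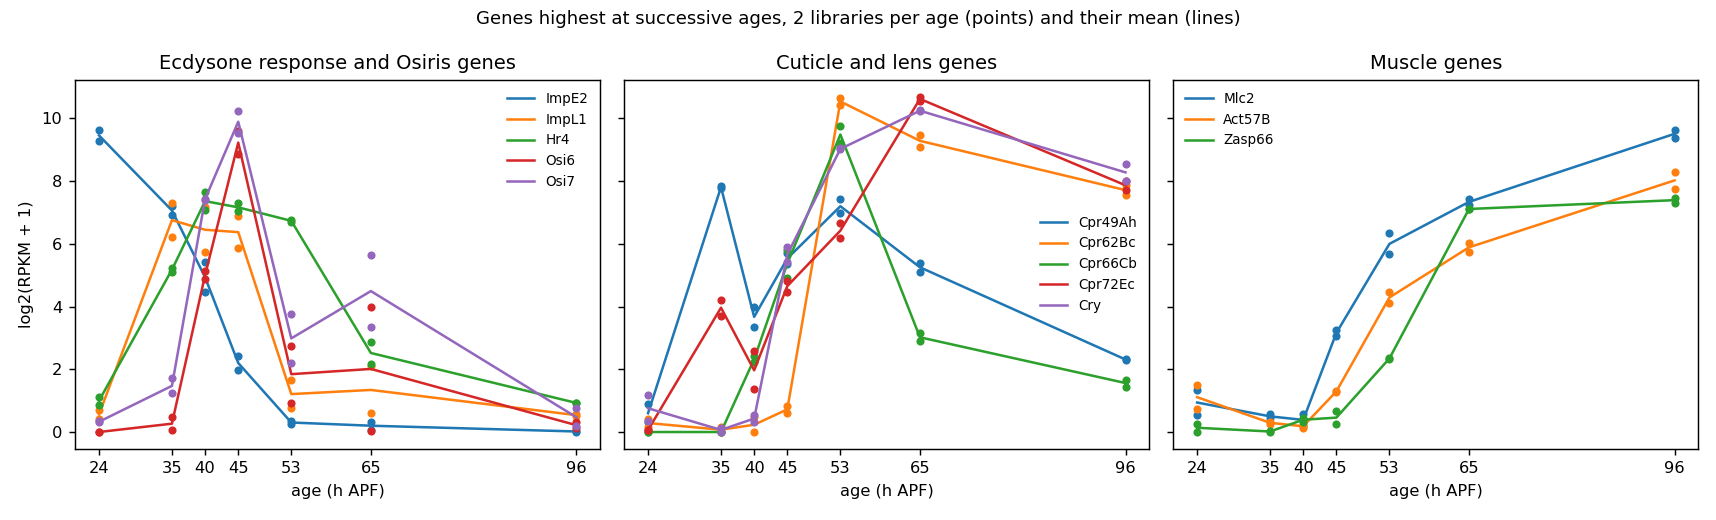
Levels as log2(RPKM + 1) (vertical axis) against age in h APF (horizontal axis) for ecdysone response and Osiris genes, for cuticle and lens genes and for muscle genes, with points for each of 2 libraries per age and lines through their mean. Osi7 stands at 976 ± 323 RPKM at 45 h and 8.13 ± 6.42 RPKM at 53 h, and Mlc2 is highest at 96 h with 729.8 ± 98.5 RPKM.

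Between 53 and 65 h opsins parted ways. Rh3 rose by 2.10 ± 0.19 while ninaE fell by 1.81 ± 0.24, from 513 ± 25.4 to 147 ± 28.8 RPKM, and Rh6 by 1.59 ± 0.21 (adjusted p = 0.000123). Rh5 rose by 0.62 ± 0.20 (adjusted p = 0.0388), a call lost when any 1 library of 35, 40, 53, 65 or 96 h was left out. Rh4 had 0.28 ± 0.24 (adjusted p = 0.426), called a rise of 0.71 only under median-ratio scaling. Gbeta76C, the eye-specific G protein beta subunit, rose by 2.75 ± 0.23, ninaC by 2.27 ± 0.21 and chp by 1.54 ± 0.21. The lens gene Cpr72Ec rose by 4.20 ± 0.33 to 1575 ± 118 RPKM, vir-1 by 5.80 ± 0.27 and Osi20 by 5.61 ± 0.16, while Cpr66Cb, high at 53 h, fell by 6.46 ± 0.28. Hr4 and Eip75B fell back, with changes of -4.21 ± 0.24 and -2.85 ± 0.28, and ftz-f1, a nuclear receptor gene that follows the ecdysone pulse, rose by 2.54 ± 0.19.

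Of 33 phototransduction genes 14 rose, 7 fell and 12 did not pass the test (14 and 7 adjusted over the list alone, camera adjusted p = 7.14e-06, adjusted p = 0.234 with an estimated correlation). For histamine transmission 4 of 6 genes rose, 0 fell and 2 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.000183, adjusted p = 0.0387 with an estimated correlation). The guidance and adhesion genes otk, Dscam2 and CadN fell by 4.25 ± 0.21, 2.44 ± 0.35 and 1.42 ± 0.29. For axon guidance 1 of 51 genes rose, 28 fell and 22 did not pass (1 and 31 adjusted over the list alone, camera adjusted p = 0.000118, adjusted p = 0.817 with an estimated correlation). fru, encoding a transcription factor known for its role in male behaviour, rose by 3.33 ± 0.19, and dve, a repressor of opsin genes, fell by 2.09 ± 0.27. The vesicle gene synaptogyrin rose by 2.27 ± 0.17 and brp fell by 1.31 ± 0.23. Among cuticle proteins 29 of 64 genes rose, 11 fell and 24 did not pass (30 and 13 adjusted over the list alone, camera adjusted p = 5.03e-12, adjusted p = 0.0387 with an estimated correlation). Of the muscle list 13 of 20 genes rose, 1 fell and 6 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 1.55e-12, adjusted p = 0.0387 with an estimated correlation). In the proteasome 0 of 31 genes rose, 25 fell and 6 did not pass (0 and 26 adjusted over the list alone, camera adjusted p = 3.98e-06, adjusted p = 0.234 with an estimated correlation). In all 2826 genes were called, 660 higher and 2166 lower, the median shift was -0.25, and median-ratio scaling gave 1409 higher and 1117 lower. Without replicate 1 of 65 h the count was 1560.

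In the last interval, 65 to 96 h, ninaE rose by 8.59 ± 0.24, Rh4, Rh5 and Rh6 by 6.34 ± 0.24, 5.99 ± 0.20 and 8.18 ± 0.21, Arr1 by 8.55 ± 0.26 to 5026 ± 273 RPKM, and trpl, the second light-activated channel, by 8.09 ± 0.20 to 1012 ± 80.7 RPKM (adjusted p = 1.02e-10). Tetraspanin genes moved in opposite directions, since Tsp42En rose by 8.00 ± 0.25 and Tsp47F fell by 6.23 ± 0.28. nrv1, a subunit of the sodium pump, rose by 6.12 ± 0.26 and retinin by 7.08 ± 0.21. alphaTub84B and betaTub56D, the main tubulin genes, fell by 3.88 ± 0.22 and 3.86 ± 0.20, while chp had 0.21 ± 0.21 (adjusted p = 0.441), called a rise of 0.78 only under median-ratio scaling.

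In the phototransduction list 24 of 33 genes rose, 3 fell and 6 did not pass (24 and 3 adjusted over the list alone, camera adjusted p = 1.75e-12, adjusted p = 0.0875 with an estimated correlation). For histamine transmission 5 of 6 genes rose, 0 fell and 1 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.00731, adjusted p = 0.112 with an estimated correlation). Among cytoskeletal genes 6 of 50 genes rose, 34 fell and 10 did not pass (7 and 34 adjusted over the list alone, camera adjusted p = 0.00459, adjusted p = 0.629 with an estimated correlation). Among ribosomal proteins 1 of 88 genes rose, 53 fell and 34 did not pass (1 and 55 adjusted over the list alone, camera adjusted p = 0.00138, adjusted p = 0.715 with an estimated correlation). For chaperones 0 of 15 genes rose, 10 fell and 5 did not pass (0 and 10 adjusted over the list alone, 1 and 9 after median-ratio scaling, camera adjusted p = 0.0148, adjusted p = 0.574 with an estimated correlation). Hsp67Ba fell by 5.16 ± 0.24, a value made uncertain by an antisense gene over 75.9% of its exonic bases. In the proteasome, unlike in the preceding step, 18 of 31 genes rose, 2 fell and 11 did not pass (18 and 2 adjusted over the list alone, camera adjusted p = 0.000164, adjusted p = 0.262 with an estimated correlation). Cpr30F fell by 5.58 ± 0.28. Among cuticle proteins 13 of 64 genes rose, 33 fell and 18 did not pass (15 and 33 adjusted over the list alone, camera adjusted p = 0.118, adjusted p = 0.629 with an estimated correlation). Of the muscle list 15 of 20 genes rose, 1 fell and 4 did not pass (15 and 1 adjusted over the list alone, camera adjusted p = 2.36e-06, adjusted p = 0.121 with an estimated correlation). In the glial list 7 rose, 4 fell and 8 did not pass the test (7 and 4 adjusted over the list alone, camera adjusted p = 0.0687, adjusted p = 0.629 with an estimated correlation), with bnb at 4.87 ± 0.33. The neuropeptide gene CCHa1 fell by 5.97 ± 0.30, from 110.4 ± 26.4 RPKM. In all 4810 genes were called, 1610 higher and 3200 lower, the median shift was -0.27, and median-ratio scaling gave 2695 higher and 2143 lower.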

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

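Median-ratio scaling, limma-voom on recovered reads, and fits without both 40 h libraries, without both 45 h libraries, with only those of 40 h and later or with only those of 24 and 35 h were tests chosen only after the results were seen. With each library left out in turn, the other library of its age being assumed to vary like the rest, the genes changing over time numbered 8694 to 9009. Genes called ranged from 6839 to 7638 from 24 to 96 h, 4383 to 5928 from 35 to 53 h, 2849 to 4719 from 24 to 35 h, 3061 to 4962 from 35 to 40 h and 2999 to 4774 from 40 to 45 h. The ranges were 1321 (without replicate 1 of 53 h) to 3052 (without replicate 2 of 45 h) from 45 to 53 h, 1560 (without replicate 1 of 65 h) to 3707 (without replicate 2 of 45 h) from 53 to 65 h, and 3859 to 5445 from 65 to 96 h. Genes changing over time fell to 5771 at a filter of 10 RPKM, where fewer genes are tested, and to 3448 with only the 24 and 35 h libraries. From 45 to 53 h weights for libraries gave 844 genes and the 4 libraries alone 206, and from 40 to 45 h the 4 libraries alone gave 1726. All other totals of genes called or changing over time stayed within 1.5 times. Splits into higher and lower were not held to this limit. From 24 to 96 h they went from 2002 higher and 5359 lower to 3725 and 3125 under median-ratio scaling. Of 224 pairs of list and contrast 93 were called, against 10 with an estimated correlation and 141 with fry.

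Of 148 changes of named genes (145 called), 138 kept direction and call under every alternative run. From 65 to 96 h chp, at 0.21, ranged from -0.02 (without replicate 1 of 65 h) to 0.44 (without replicate 2) over libraries left out, and had 0.78 under median-ratio scaling (adjusted p = 0.00893). From 24 to 96 h brp had 0.17 under median-ratio scaling and -0.07 under quantile normalization. The call of brp from 35 to 53 h was lost without replicate 1 of 53 h (adjusted p = 0.0502), and that of repo from 45 to 53 h gained without replicate 1 of 45 h (adjusted p = 0.0129). The call of Rh5 from 53 to 65 h was lost when any 1 library of 35, 40, 53, 65 or 96 h was left out (0.48 and adjusted p = 0.2025 without replicate 1 of 53 h), without both 40 h libraries, with the block and with a pseudocount of 0.1. Rh4 was called there under median-ratio scaling (0.71, adjusted p = 0.0282). With only the 4 libraries of the contrast Syn from 40 to 45 h (adjusted p = 0.0537) and eya, ort and ro from 45 to 53 h (adjusted p = 0.0637, 0.125 and 0.0551) were not called. The cause was not tested. Genes at low levels are limited by depth, since the 3-read level of the shallowest library is 0.169 RPKM for a 2 kb gene.

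Replicate numbers do not pair the libraries. Deviations from the age mean correlated between -0.35 and 0.23 over 21 pairs of ages, with 2 above 0.1. As a block, the number left 7338 genes called from 24 to 96 h, 2116 from 45 to 53 h and 92 list calls.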

Other observations

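All tests of explanations below were chosen only after the result was seen. For the test of muscle genes outside the list, the genes were picked before their own values were looked up. Exon overlap, correlations with length and counts of genes with a dip at 40 h were also looked at. Pgi and PyK, enzymes of glycolysis, rose from 24 to 96 h by 3.07 ± 0.18 and 2.45 ± 0.22. In their list 10 of 14 genes rose, 2 fell and 2 did not pass (10 and 2 adjusted over the list alone, camera adjusted p = 0.000174, adjusted p = 0.0389 with an estimated correlation). From 65 to 96 h 12 of 14 genes rose, 1 fell and 1 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 1.25e-06, adjusted p = 0.0434 with an estimated correlation), with Gapdh1 at 3.09 ± 0.23. Over that interval the muscle median, relative to all genes, went from 2.01 to 4.08 and the glial one from 0.03 to 1.07. From 24 to 96 h VhaM9.7-a, a subunit of the vacuolar proton pump that acidifies vesicles, rose by 3.56 ± 0.23. In the list of that pump, over the same ages, 12 of 20 genes rose, 2 fell and 6 did not pass (12 and 2 adjusted over the list alone, camera adjusted p = 4.66e-05, adjusted p = 0.0456 with an estimated correlation).

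Over the same ages the antimicrobial peptide gene Dro rose by 3.12 ± 0.29 to 11.3 ± 4.3 RPKM. In the list of antimicrobial peptides and immune recognition 6 of 12 genes rose, 4 fell and 2 did not pass (6 and 4 adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.168 with an estimated correlation). Among clock genes cyc fell by 3.03 ± 0.16 while Pdp1 and tim rose by 1.92 ± 0.22 and 1.58 ± 0.18. In that list 5 of 11 genes rose, 4 fell and 2 did not pass (5 and 4 adjusted over the list alone, camera adjusted p = 0.174, adjusted p = 0.394 with an estimated correlation). Yp3, a yolk protein gene of fat body and ovary, rose by 3.07 ± 0.28. In the list of hemocytes and fat body 3 of 10 genes rose, 6 fell and 1 did not pass (3 and 7 adjusted over the list alone, 4 and 3 after median-ratio scaling, camera adjusted p = 0.746, adjusted p = 0.802 with an estimated correlation).

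Mitochondrial reads made up at least 0.524% of every library of 24 and 35 h and at most 0.008% of every later one, and ribosomal RNA at least 0.281% against at most 0.001%. Fewer glial cells and other neurons from 40 h on were argued against: mitochondrially encoded transcripts had a median of -3.02 from 35 to 45 h while the glial median was 0.40. A difference in how the libraries of 24 and 35 h were made or mapped could explain the step, but the gap between these shares is the observation itself and gives no support. It cannot be told apart from age, because no age has libraries of both kinds and the labels give no batch. A change with age itself stays open and untested.

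At 40 h the glial median lay 0.94 and that of other neurons 0.64 below the mean of 35 and 45 h, relative to all genes. A dependence on transcript length was argued against, since the glial median was -0.88 after removal of a trend on length. A smaller share of RNA from other cells at 40 h could lower all such lists alike. All 5 lists lay lower over all members (cones, pigment and lens cells -0.29, hemocytes -0.33, proliferating cells -0.41), which was the first test made. Over members of at least 5 RPKM, a test added after that, the medians were unequal (glia -1.59, other neurons -2.04, cones, pigment and lens cells -0.58, proliferating cells -0.60, 2 hemocyte members 0.44), but with a permutation p of 0.0809 for a difference between lists the few members leave this open. A dip at 40 h was not particular to markers of other cells. By the same measure over all members, Beat and Side proteins lay at -1.01, the proteasome at -0.86 and leucine-rich repeat proteins at -0.52. Oxidative phosphorylation (0.96), ribosomal proteins (0.86) and the rhabdomere list (0.76) lay higher instead.

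Muscle genes stood higher from 45 h on. A shift of scale was argued against by its direction. From 24 to 96 h the median of all genes changed by -0.92, and median-ratio scaling moved it up by 1.04. Such a shift would lower genes at 96 h, while the list's median rise was 5.12. The size of 1.04 is therefore no measure of a rise that it could give. Muscle cells carried over in the dissection could be the source, although the purification on ribosomes tagged in photoreceptors is meant to remove such RNA. A test of other muscle genes could have spoken against them but cannot support them, since muscle genes expressed in photoreceptors would pass it too: 4 of 4 tested muscle genes outside the list were called higher at 96 h, Mlp60A by 5.64 ± 0.21, Mlp84B by 5.92 ± 0.23, Lmpt by 2.22 ± 0.30 and Mp20 from 0 to 35.4 RPKM, while Unc-89 and sals were not among the tested genes. These genes were picked after the list's rise and after a first test that was set aside because it sets single libraries against each other (16 of 20 members higher in replicate 1 of 53 h, exact sign test p = 0.0118, against 46.7% of all genes).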
